A study of Homo sapiens with 12 samples.

How the data were processed

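Gene expression was measured on 12 single Affymetrix Human Gene ST arrays, 3 for each combination of cell line (JHU-029 or FaDU) and lentiviral shRNA (a control vector, shControl, or an shRNA against TP63, shTP63). RNA was collected 72 hours after knockdown. The deposited values are given as intensity, which the authors made by robust multi-array averaging (RMA), an array method that corrects background, normalises probe distributions by quantiles and summarises probes by median polish. RMA and R version 2.15.1 are named per the submitters' processing notes; which RMA implementation and probe set definition were used, and whether the 12 arrays were normalised together, is not given in the sources used here. The choices described here were made before the data were examined, except where stated otherwise. Those choices assumed a log2 scale, while the table held linear intensity, so the values were put on a log2 scale before any test, as had been planned for that case. The median linear intensity of an array lay between 88.2 and 94.6 over 32321 probe sets. No counts stand behind array values, and the number of arrays limits the precision. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples.

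Probe sets were named through the array's own table of gene symbols. Of the 32321 probe sets, 19159 were listed with 1 gene symbol, 1387 with several and 11775 were not listed. Of the 19159, 19128 matched a gene of the reference table by Entrez gene ID, and 0 symbols changed through the match. Probe sets without a single symbol were left out of the gene tests. The probe set with the highest mean over all arrays stood for a gene, which gave 18405 genes, 637 of them with more than 1 probe set. The 23 measured genes of the Y chromosome and XIST are never named. The level of TP63 itself is not analysed here.

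A linear model of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and an empirical Bayes prior of 4.16 degrees of freedom. The contrasts were shTP63 minus shControl in JHU-029, the same in FaDU, the difference between these effects (FaDU effect minus JHU-029 effect), and FaDU shControl minus JHU-029 shControl. Genes changed the same way in both lines were those past the threshold in both with the same sign. P-values are two-sided moderated tests from limma, adjusted by Benjamini and Hochberg over all 18405 genes within a contrast, with a threshold of 0.05. No fold minimum and no filter on dim probe sets was applied. A change is described as a rise or a fall only where its adjusted p was under that threshold. Standard errors (SE) are those of the limma fit, and standard deviations (SD) are taken over the 3 arrays of a group.

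25 gene lists held 745 distinct genes, of which 686 were measured. They were basal keratinocyte and p63-associated genes (TP63 left out), keratinocyte differentiation genes, a published set of YAP/TAZ target genes, Hippo pathway components, SWI/SNF subunits, genes of the distal 3q region often amplified in squamous carcinoma, S phase genes, G2 and M phase genes, interferon-stimulated genes, genes activated by p53-family proteins, BCL2 family and apoptosis inhibitors, mesenchymal genes, epithelial junction genes, simple and secretory epithelium genes, NF-kB and inflammation genes, unfolded protein response genes, heat shock and immediate early genes, hypoxia-inducible genes, cholesterol and fatty acid synthesis genes, EGFR and FGFR signalling genes, Notch genes, cytosolic ribosomal proteins, and markers of fibroblasts, immune cells and endothelial cells. Some lists share genes. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 25 lists of a contrast. Camera with a correlation estimated from the data and fry were alternatives. Fry asks whether a list's genes move, on balance, in one direction and compares the list with no other genes. Counts of list members are given over all genes tested and adjusted over the list alone.

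Genes were named by a fixed rule. It took ACTL6A, WWC1, YAP1, CCN2, CCN1, KRT5 and KRT14 in all cases. For each line it took the 10 genes with the largest rise and the 10 with the largest fall whose 3 knockdown arrays all lay on one side of the 3 control arrays. It took the 10 highest and 10 lowest by mean change among genes changed the same way, and the 10 largest in each direction for the other contrasts. For each list it took up to 2 members per direction and line. Genes named outside this rule are marked as chosen after their values were seen.

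The pipeline was tested on simulated data in which 200 of 18405 genes were changed in each line, with 30 further genes shifted by 0.2 as a list. At log2 changes of 0.25, 0.5 and 1, 13.2%, 94.2% and 100% were recovered with the changes placed in JHU-029. With the changes placed in FaDU, 12.9%, 84.6% and 100% were recovered. Both runs used the same spread per gene, pooled over the 4 groups, so they do not compare the lines. False calls made up 5.59% and 4.35% of the calls. Noise was drawn independently for each gene and array, so these shares do not cover noise shared by genes or deviating arrays. Far fewer genes were changed than the 26.6% called in FaDU, so the shares recovered do not carry over to that contrast. The labels do not say whether replicate numbers pair knockdown with control arrays. Residuals of arrays with the same number correlated across genes at -0.34, -0.01 and -0.20 in JHU-029 and at -0.08, -0.07 and 0.01 in FaDU. No positive pairing showed. The titles of the FaDU arrays number them 2 to 4 where the descriptions say 1 to 3, and the titles of FaDU shControl replicates 1 and 2 carry an extra word. The labels name 3 growth media without assigning them to the lines.

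The alternatives were the replicate number as a fixed or a random block (statmod 1.5.0), a variance prior with a trend or made robust, array weights, each line fitted alone, a filter on dim probe sets, the mean of a gene's probe sets, every probe set as its own item, 3 other scalings (quantile normalisation again, equal medians, cyclic loess), an adjusted p under 0.01, a 2-fold minimum, and leaving out each of the 12 arrays in turn. For the lists, leaving out genes that stand on several lists was a further alternative. The scalings and the leaving out of single arrays for the lists, and the joint removal of the 2 FaDU controls with the extra title word, were chosen after seeing the data.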

Results

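TP63 encodes p63, the transcription factor of basal keratinocytes, and the series asks how p63 and the SWI/SNF subunit ACTL6A act on Hippo-YAP signalling in squamous carcinoma. JHU-029 and FaDU, both established lines of head and neck squamous cell carcinoma, received a control vector or an shRNA against TP63. The resulting 4 groups held 3 arrays each, and 18405 genes were compared 72 hours after knockdown. Across probe sets, log2 intensities of arrays from 1 group correlated at 0.993 to 0.997, and those of arrays from different lines at 0.940 to 0.951. The median SD between arrays of a group was 0.0798 in JHU-029 and 0.105 in FaDU on the log2 scale.

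Of the genes nearest to the series' question, KRT5 (probe set 7963427), which with KRT14 (probe set 8015366) forms the keratin pair of basal keratinocytes, fell by 1.41 in FaDU on the log2 scale (SE 0.05, adjusted p = 1.37e-08, n = 3 arrays per group). Its mean log2 intensity went from 12.39 ± 0.0023 (SD, n = 3) to 10.98 ± 0.08. KRT14 fell by 0.43 in FaDU (SE 0.07, adjusted p = 0.000818). In JHU-029 the changes were -0.11 for KRT5 (SE 0.05, adjusted p = 0.369) and -0.05 for KRT14 (SE 0.07, adjusted p = 0.872), neither past the threshold. Control means there were higher, 13.25 for KRT5 and 12.93 for KRT14, against 12.39 and 9.81 in FaDU. Whether such high intensities compress a change in JHU-029 was not tested. The difference between the lines was -1.30 for KRT5 (adjusted p = 1.9e-06) and -0.38 for KRT14 (adjusted p = 0.0294). The KRT14 difference missed the threshold in 7 of the 12 fits that left out 1 array (JHU-029 shControl replicates 2 and 3, JHU-029 shTP63 replicates 2 and 3, FaDU shControl replicate 2, FaDU shTP63 replicates 1 and 3), with adjusted p values of up to 0.08. It also missed the threshold with every probe set as its own item (adjusted p = 0.0595) and with a fixed replicate block (adjusted p = 0.0742).

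WWC1 (probe set 8109773), an upstream activator of the Hippo kinases, rose in both lines, by 0.53 in FaDU (SE 0.06, adjusted p = 6.02e-05) and by 0.32 in JHU-029 (SE 0.06, adjusted p = 0.0182), and the lines did not differ detectably (adjusted p = 0.159). YAP1 (probe set 7943398), the transcriptional co-activator that Hippo signalling restrains, fell by 0.47 in FaDU (SE 0.05, adjusted p = 1.33e-05) and by 0.24 in JHU-029 (SE 0.05, adjusted p = 0.0172). CCN1 (probe set 7902687) and CCN2 (probe set 8129562), secreted matrix proteins and well-known YAP targets, rose in FaDU by 0.37 (SE 0.07, adjusted p = 0.00204) and 0.29 (SE 0.09, adjusted p = 0.0238). In JHU-029 they changed by 0.10 (adjusted p = 0.62) and 0.04 (adjusted p = 0.922), and the difference between the lines did not pass for either (adjusted p = 0.114 and 0.212). For CCN1 that difference, 0.27, passed with a trend in the variance prior (adjusted p = 0.0422) and without FaDU shTP63 replicate 1 (0.345, adjusted p = 0.025), and elsewhere its adjusted p reached 0.302. ACTL6A (probe set 8084067) stayed within the error in JHU-029 at 0.00 (SE 0.06, adjusted p = 0.99), with a sign that turned under 2 other scalings, and in FaDU at -0.06 (SE 0.06, adjusted p = 0.536). The WWC1 call in JHU-029 was lost without JHU-029 shControl replicate 2, shControl replicate 3 or shTP63 replicate 2 (adjusted p of up to 0.0971), and the YAP1 call there without any shControl replicate or shTP63 replicate 3 (up to 0.0827). The YAP1 difference between the lines, -0.24 (adjusted p = 0.0357), was lost in 9 of 12 such fits (up to 0.0978). These were all but the fits without JHU-029 shTP63 replicate 1, FaDU shControl replicate 2 or FaDU shTP63 replicate 1. That difference was also lost under each other scaling and with every probe set as its own item (0.0555). A fixed (0.129) or random replicate block (0.0532) ended it too. The CCN2 call in FaDU was lost without FaDU shControl replicate 1 (0.0977) or shTP63 replicate 2 (0.0972), and with each line fitted alone (0.073). With the 2 FaDU controls that carry an extra title word left out, which leaves 1 FaDU control array, the change in FaDU was 0.34 for CCN1 (SE 0.11, adjusted p = 0.0538) and 0.19 for CCN2 (SE 0.11, adjusted p = 0.294). The CCN1 call ended mainly through the larger error of fewer arrays. The differences between the lines for YAP1 (-0.24, adjusted p = 0.101) and KRT14 (-0.32, adjusted p = 0.154) also missed the threshold there.

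**Figure D1:**
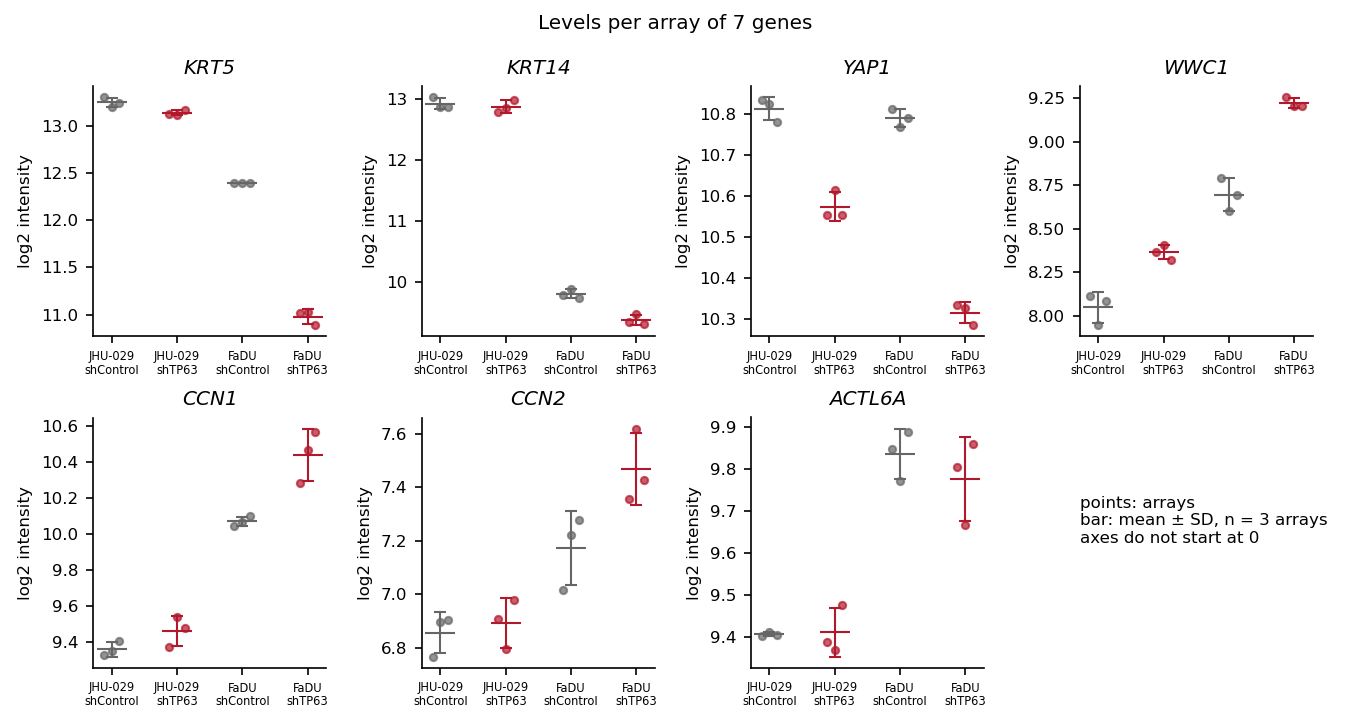
Log2 intensity (vertical axes, which do not start at 0) of 7 genes on each of the 12 arrays, by cell line and shRNA (horizontal axes); points are arrays and bars the mean ± SD of 3 arrays. KRT5 went from a mean of 12.39 to 10.98 in FaDU, and YAP1 was lower after knockdown in both lines, from 10.81 to 10.57 in JHU-029 and from 10.79 to 10.32 in FaDU.

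In JHU-029, the largest rises after TP63 knockdown among genes whose 3 knockdown arrays all lay above the 3 controls were those of SYT14, a synaptotagmin (2.46-fold; log2 1.30, SE 0.12, adjusted p = 0.000118, n = 3 arrays per group), MYPN, a sarcomere protein (2.20-fold), PLAC8 (2.17-fold), EVI2B (2.11-fold) and SYTL2, a vesicle transport protein (2.09-fold). The ubiquitin ligase FBXO32 (1.90-fold), the metalloprotease ADAM19 (1.86-fold), the serine protease PRSS22 (1.81-fold) and the cytidine deaminase CDA (1.78-fold) also rose. CMKLR2 rose 2.07-fold, a call lost without shControl replicate 2, shTP63 replicate 2 or shTP63 replicate 3 (adjusted p of up to 0.0628). The largest falls were those of ADH7, a retinol-oxidising alcohol dehydrogenase (2.31-fold; log2 -1.21, SE 0.13, adjusted p = 0.000347), the apoptosis gene TP53AIP1 (2.25-fold), the chemokine CXCL14 (2.24-fold), the carbonic anhydrase CA12 (2.07-fold) and the transcription factor FOXP2 (2.04-fold). GOLGA7B (1.81-fold), the glycolytic enzyme TPI1 (1.79-fold) and the matrix metalloprotease MMP10 (1.78-fold) fell as well. PALMD fell 1.80-fold, lost without any shControl replicate, shTP63 replicate 1 or shTP63 replicate 2 (adjusted p of up to 0.0896). The connexin GJB6 fell 1.70-fold, lost without shControl replicate 1 or 3 (up to 0.0579). Many of these folds have at least 1 group mean below the JHU-029 array medians of 6.46 to 6.51, which makes their size and rank uncertain. Control means were 6.05 for SYT14, 6.01 for CMKLR2, 5.79 for SYTL2, 5.15 for MYPN, 4.91 for PLAC8 and 4.35 for EVI2B. Knockdown means were 6.36 for MMP10, 5.92 for TP53AIP1, 5.74 for ADH7 and 4.58 for FOXP2.

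Basal and p63-associated genes were lower in JHU-029 as a group, with 5 of 37 measured members falling and 0 rising (11 falling adjusted over the list alone). S100A2 fell by 0.47 (SE 0.06), and NECTIN1, a cell adhesion protein, fell by 0.36 (SE 0.06). The list's median change was -0.10, with a camera adjusted p = 4.71e-06 and an adjusted p = 0.249 with an estimated correlation. EGFR and FGFR signalling genes also moved down, with 6 of 26 falling and 0 rising (adjusted over the list alone, 11 falling and 1 rising) and a median of -0.08 (adjusted p = 8.65e-05, and adjusted p = 0.249 with an estimated correlation). The ERK phosphatase DUSP6 fell by 0.61 (SE 0.07). Without shTP63 replicate 2 the median was -0.12. Cell cycle genes moved up: 3 of 52 G2 and M phase genes rose (15 rising and 1 falling adjusted over the list alone), among them the mitotic kinesin KIF20B by 0.44 (SE 0.06), with a median of 0.11 and adjusted p = 1.12e-09. Of 38 S phase genes 4 rose (6 adjusted over the list alone), with a median of 0.09 and adjusted p = 8.65e-05. These became adjusted p = 0.249 with an estimated correlation for G2 and M phase and adjusted p = 0.429 with an estimated correlation for S phase.

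Epithelial junction genes were higher in JHU-029, with 5 of 26 rising and 1 falling (8 and 4 adjusted over the list alone, median 0.05, adjusted p = 0.0117, and adjusted p = 0.429 with an estimated correlation). The tight junction proteins CLDN1 and CLDN7 rose by 0.80 (SE 0.07) and 0.62 (SE 0.08), and the connexin GJB2 fell by 0.76 (SE 0.11, adjusted p = 0.00323). Without shControl replicate 1 the median was 0.09. Genes of the distal 3q region had 2 of 31 rising (3 adjusted over the list alone, median 0.04, adjusted p = 0.0323, and adjusted p = 0.525 with an estimated correlation), CLDN1 again among them. That call was lost without shControl replicate 3 (0.0909), shTP63 replicate 2 (0.159) or shTP63 replicate 3 (0.0885), the median being 0.02 without shTP63 replicate 2 and 0.08 without shTP63 replicate 1. It was also lost under cyclic loess (0.0823) and with genes of several lists left out (0.096). Cholesterol and fatty acid synthesis genes had 1 rising and 1 falling of 27 (the same adjusted over the list alone), with a median of -0.06 (adjusted p = 0.0226, and adjusted p = 0.525 with an estimated correlation). It was lost without shControl replicate 1 (0.216) or shTP63 replicate 1 (0.355; median -0.04).

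The other 18 lists did not pass in JHU-029 (camera adjusted p from 0.101 to 0.769). Of 50 keratinocyte differentiation genes 5 rose and 1 fell, the same numbers adjusted over the list alone. The transcription factor GRHL1 rose by 0.50 (SE 0.08). Of 22 YAP/TAZ targets 2 rose and 1 fell (5 and 2 adjusted over the list alone), the receptor kinase AXL rising by 0.48 (SE 0.07) and TGFB2 by 0.42 (SE 0.07). Of 40 interferon-stimulated genes 2 rose (2 adjusted over the list alone), with a median of 0.06. That list passed without shControl replicate 1 (median 0.10, adjusted p = 0.00551) or without shTP63 replicate 1 (median 0.12, adjusted p = 1.11e-06). With all arrays and an estimated correlation no list passed in JHU-029 (lowest adjusted p = 0.249), and the correlation was not estimated in fits without 1 array. Hypoxia-inducible genes, with 1 of 24 falling, passed without shTP63 replicate 2 (median -0.06, adjusted p = 0.0496) or replicate 3 (median -0.05, adjusted p = 0.04), and under cyclic loess (median -0.04, adjusted p = 0.0428). IL6 rose by 0.59 (SE 0.07) among NF-kB and inflammation genes, of which 2 rose and 3 fell of 31 (2 and 4 adjusted over the list alone). Of the markers of fibroblasts (13 measured), immune cells (14) and endothelial cells (10), 0 passed by limma. Median and mean differed in sign for the fibroblast and immune lists.

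Across JHU-029, 580 genes (3.15%) passed the threshold, 332 higher and 248 lower, and 2728 had an unadjusted p under 0.05. A change of at least 2-fold was reached by 11 of them, 6 higher and 5 lower. The count was between 229 and 273 without JHU-029 shControl replicate 1 (269), 2 (232) or 3 (229) or shTP63 replicate 2 (238) or 3 (273). Without JHU-029 shTP63 replicate 1, 485 genes passed, 70.3% of them higher against 57.2% with all arrays. The share was 65.4% without shControl replicate 1 and 50.9% without shTP63 replicate 3, so the balance of rises and falls depended on single arrays. Fry passed 4 of the 25 lists.

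In FaDU, the largest rises were those of MGAT4A, an enzyme of N-glycan branching (5.53-fold; log2 2.47, SE 0.10, adjusted p = 1.44e-08, n = 3 arrays per group), the ferroxidase CP (4.62-fold), the interferon-inducible GTPase GBP2 (4.35-fold), SLC46A3 (4.34-fold), the selenium transporter SELENOP (3.70-fold) and complement C3 (3.67-fold). STEAP4, a metalloreductase, rose 3.66-fold, ENPP5 3.57-fold, the translation regulator CPEB4 3.06-fold and the siderophore-binding protein LCN2 3.04-fold. The largest falls were those of the cytokine IL1A (6.43-fold; log2 -2.69, SE 0.12, adjusted p = 1.95e-08), MMP10 (6.30-fold), the ERBB ligand NRG1 (4.72-fold), the protocadherin FAT2 (3.80-fold), SERPINB13 (3.72-fold), AHNAK (3.50-fold) and DUSP6 (3.48-fold). DPH2, an enzyme of diphthamide synthesis, fell 3.46-fold, C11orf24 3.05-fold and the calcium sensor VSNL1 3.02-fold. A second probe set gave a change of 1.28 against 2.12 for GBP2 and of -1.72 against -2.24 for NRG1. Some of these folds have at least 1 group mean below the FaDU array medians of 6.52 to 6.56, which makes their size and rank uncertain. Control means were 6.26 for MGAT4A, 5.15 for SLC46A3 and 5.07 for GBP2, and knockdown means 6.31 for VSNL1, 5.73 for IL1A and 5.66 for NRG1.

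Basal and p63-associated genes fell together in FaDU: 30 of 37 measured members fell and 0 rose (31 falling and 1 rising adjusted over the list alone). FAT2 fell by 1.93 (SE 0.11), and the metalloprotease ADAMTS1 fell by 1.48 (SE 0.11). The median change was -0.55, with a camera adjusted p = 3.48e-21, and the call held with an estimated correlation (adjusted p = 0.0215), the only one of the 25 lists in FaDU for which it did. EGFR and FGFR signalling genes moved down, with 9 of 26 falling and 5 rising (10 and 5 adjusted over the list alone, median -0.14, adjusted p = 0.00677, and adjusted p = 0.286 with an estimated correlation). The EGFR ligand TGFA fell by 1.21 (SE 0.08), while the receptor ERBB3 rose by 0.63 (SE 0.05). Cholesterol and fatty acid synthesis genes were lower, with 16 of 27 falling and 1 rising (17 and 1 adjusted over the list alone, median -0.21, adjusted p = 7.98e-05, and adjusted p = 0.365 with an estimated correlation). DHCR7, the last enzyme of cholesterol synthesis, fell by 0.42 (SE 0.06). Unfolded protein response genes had 10 of 22 falling and 1 rising (11 and 1 adjusted over the list alone, median -0.17, adjusted p = 0.000747, and adjusted p = 0.365 with an estimated correlation). CHAC1, which degrades glutathione, fell by 0.99 (SE 0.10), and the asparagine synthetase ASNS fell by 0.89 (SE 0.06).

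Interferon-stimulated genes rose in FaDU, with 25 of 40 rising and 0 falling (28 rising adjusted over the list alone). IFI27 rose by 0.94 (SE 0.08) and OAS2, which senses double-stranded RNA, by 0.89 (SE 0.09). The median was 0.35 (adjusted p = 1.95e-09, and adjusted p = 0.365 with an estimated correlation). Simple and secretory epithelium genes had 9 of 26 rising and 1 falling (13 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.000747, and adjusted p = 0.122 with an estimated correlation), with the mucins MUC1 at 1.35 (SE 0.10) and MUC20 at 1.24 (SE 0.11). YAP/TAZ targets had 13 of 22 rising and 2 falling (13 and 3 adjusted over the list alone, median 0.24, adjusted p = 0.0126, and adjusted p = 0.122 with an estimated correlation). TGFB2 rose by 1.24 (SE 0.07) and CCDC80, a matrix protein, by 1.13 (SE 0.10), whereas FJX1 fell by 1.33 (SE 0.10) and the growth arrest gene GADD45A fell by 1.18 (SE 0.06). Beside these lists, the endothelial cadherin CDH5 rose by 1.00 (SE 0.07) and the monocyte marker CD14 by 0.51 (SE 0.09), although the marker lists of endothelial cells (2 of 10 rising), immune cells (1 of 14) and fibroblasts (1 of 13, FBLN1 at 0.24, SE 0.06) did not pass (adjusted p = 0.267, 0.459 and 0.231); the counts were the same adjusted over each list alone. The other endothelial rise, ESAM at 0.30 (SE 0.09), was lost without FaDU shControl replicate 2 or shTP63 replicate 3 (adjusted p of up to 0.0979).

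S phase genes had 12 of 38 falling and 2 rising in FaDU (13 and 2 adjusted over the list alone, median -0.06, adjusted p = 0.0182, and adjusted p = 0.54 with an estimated correlation). CDCA7 fell by 0.90 (SE 0.06), and the cyclin CCNE2 rose by 1.07 (SE 0.06). The list lost its call without shControl replicate 1 (0.0856; median -0.04) or shTP63 replicate 1 (0.0839), under quantile normalisation again (0.099) and under cyclic loess (0.103). Heat shock and immediate early genes had 7 of 18 falling (7 adjusted over the list alone, median -0.09, adjusted p = 0.0392, and adjusted p = 0.365 with an estimated correlation), with the co-chaperone BAG3 at -0.56 (SE 0.06). They lost the call without shControl replicate 3 (0.0708), shTP63 replicate 2 (0.0515) or shTP63 replicate 3 (0.0553), and under quantile normalisation again (0.0999) and cyclic loess (0.103). G2 and M phase genes had 16 of 52 falling and 6 rising (17 and 7 adjusted over the list alone; adjusted p = 0.107), and passed without shControl replicate 2 (adjusted p = 0.0376). CDCA8, of the chromosomal passenger complex, fell by 1.20 (SE 0.11).

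In the remaining lists, members moved in both directions in FaDU and the lists did not pass as tested with all members. Of 34 Hippo pathway components 9 rose and 8 fell (9 and 9 adjusted over the list alone; adjusted p = 0.957), AMOT rising by 0.78 (SE 0.09) and its relative AMOTL1 standing at -0.99 (SE 0.07). Of 25 SWI/SNF subunits 4 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.957), with PBRM1 at 0.41 (SE 0.08) and ARID1A at -0.40 (SE 0.05). Of 31 distal 3q genes 10 rose and 7 fell (11 and 8 adjusted over the list alone; adjusted p = 0.459). Of 50 keratinocyte differentiation genes 8 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.267), with the protease inhibitor SLPI at 1.31 (SE 0.10) and the kallikrein KLK10 at -0.72 (SE 0.06). Of 26 genes activated by p53-family proteins 5 rose and 10 fell (6 and 10 adjusted over the list alone; adjusted p = 0.251), with TP53INP1 higher (adjusted p = 0.000265) but dim, at 4.71 in controls and 5.88 after knockdown, and SFN at -1.07 (SE 0.06). Of 18 BCL2 family and apoptosis genes 4 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.157), the death effector BCL2L11 rising by 0.39 (SE 0.07), and the list passed with genes of several lists left out (median 0.12, adjusted p = 0.0331). Of 34 mesenchymal genes 6 rose and 9 fell, the same adjusted over the list alone (adjusted p = 0.499), with SNAI2, a repressor of epithelial genes, at -1.43 (SE 0.06) and FN1 at 0.34 (SE 0.06).

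Epithelial junction genes had 6 of 26 rising and 6 falling in FaDU (9 and 7 adjusted over the list alone; adjusted p = 0.805), with the desmosomal cadherins DSC3 at -0.93 (SE 0.08) and DSG3 at -0.82 (SE 0.09) and the tight junction protein TJP3 at 0.88 (SE 0.10). NF-kB and inflammation genes had 7 of 31 rising and 8 falling, the same adjusted over the list alone (adjusted p = 0.873), with CFB at 1.54 (SE 0.09; 1.41 and 0.79 on its other probe sets) and IL1B at -1.46 (SE 0.08). Hypoxia-inducible genes had 9 of 24 rising and 7 falling, the same adjusted over the list alone (adjusted p = 0.276), with VEGFA at -0.74 (SE 0.06). Notch genes had 8 of 20 falling and 2 rising, the same adjusted over the list alone (adjusted p = 0.0844), with the ligand JAG1 at -1.44 (SE 0.08), and passed without FaDU shControl replicate 3 (adjusted p = 0.0225). Cytosolic ribosomal proteins had 4 of 49 falling and 1 rising (4 and 0 adjusted over the list alone; adjusted p = 0.6). Median and mean differed in sign for the Hippo, SWI/SNF, p53, mesenchymal, NF-kB and ribosomal lists, for example 0.05 and -0.14 for the mesenchymal genes. Among the list members named for FaDU, ADAMTS1 (knockdown mean 5.54), AMOT (control mean 5.57), ESAM (5.92) and FN1 (6.09) were dim as well.

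Across FaDU, 4901 genes (26.6%) passed, 2292 higher and 2609 lower, of which 67 and 89 reached a 2-fold change. The majority of falls turned under some other scalings, 51.9% being higher after quantile normalisation again and 50.3% with cyclic loess. With equal medians it stayed, 43.9% being higher. Fry passed 18 of the 25 lists. With the 2 FaDU controls that carry an extra title word left out, which leaves 1 control array, 3569 genes passed.

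**Figure D2:**
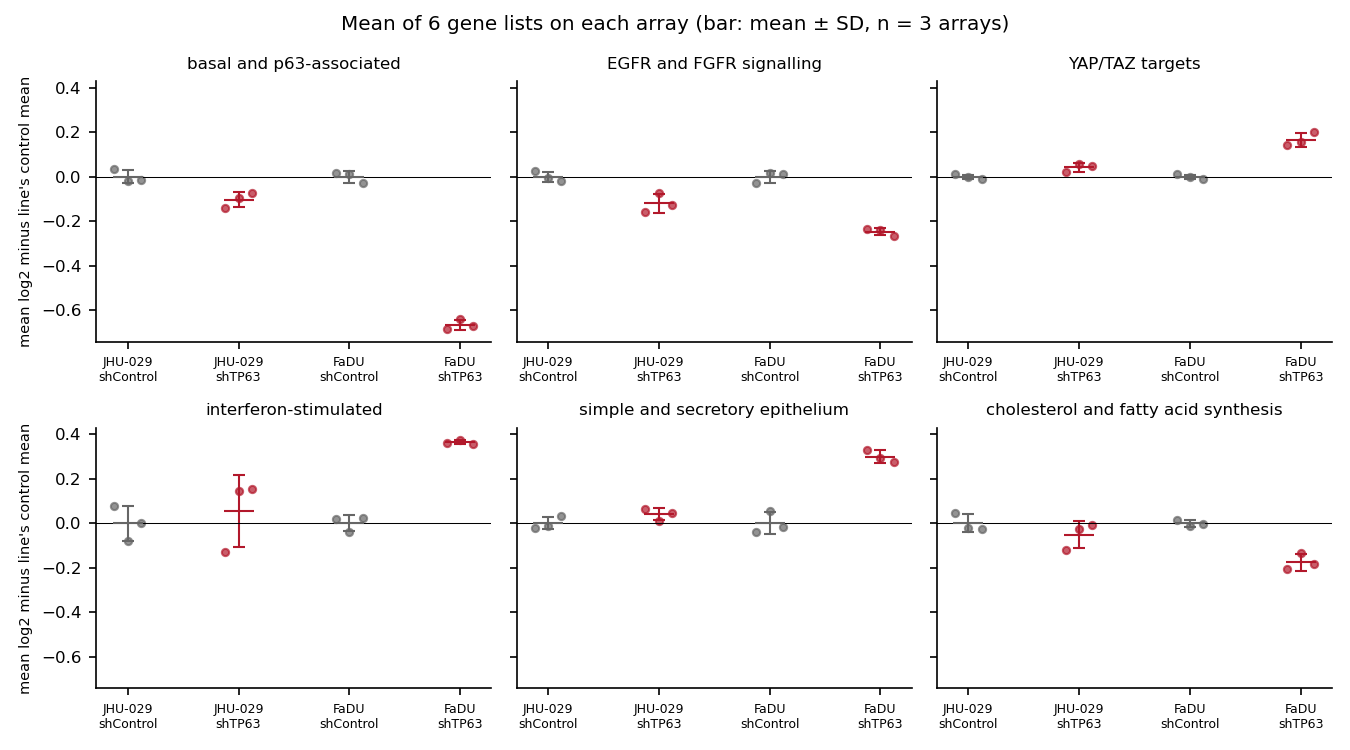
Mean log2 value of 6 gene lists on each array minus the mean of the same line's control arrays (vertical axis), by cell line and shRNA; points are arrays and bars the mean ± SD of 3 arrays. The interferon-stimulated genes lay between 0.36 and 0.38 on the FaDU knockdown arrays, and at -0.13, 0.15 and 0.15 on those of JHU-029.

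Genes changed the same way in both lines show how much of the response to the shRNA against TP63 was shared. The labels distinguish no separate shRNAs against TP63, and its level is not analysed here. Sharing therefore does not separate loss of p63 from other effects of the shRNA. MMP10 fell 1.78-fold in JHU-029 and 6.30-fold in FaDU (log2 -0.83 and -2.66, SE 0.08, n = 3 arrays per group), DPH2 1.61-fold and 3.46-fold, DUSP6 1.53-fold and 3.48-fold, TMEM109 1.70-fold (log2 -0.76) and, on the log2 scale, by -1.535 in FaDU, the kinase PRKCH 1.62-fold and 2.61-fold, and C11orf24 1.29-fold and 3.05-fold. The glycolytic enzyme TPI1 fell 1.79-fold and 2.42-fold, a second probe set giving changes of -0.91 and -0.53. EVI2B rose 2.11-fold in JHU-029 and 1.98-fold in FaDU, FBXO32 1.90-fold and 1.96-fold, PGM2L1 1.68-fold and 2.26-fold, the secreted netrin NTN4 1.69-fold and 1.95-fold, TIMP2, an inhibitor of metalloproteases, 1.54-fold and 2.34-fold, TGFB2 1.33-fold and 2.36-fold, and MYPN 2.20-fold and 1.39-fold.

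For 6 further shared genes named by the rule, the JHU-029 call depended on single JHU-029 arrays. IL1A (-0.49 in JHU-029, -2.69 in FaDU) was lost without any of the 6 JHU-029 arrays or FaDU shControl replicate 3 (adjusted p of up to 0.145). NRG1 (-0.59, -2.24) and AHNAK (-0.51, -1.81) were lost without any of the 6 JHU-029 arrays (up to 0.0948 and 0.0726). STEAP4 (0.47, 1.87), dim in JHU-029 with a control mean of 4.25, was lost without each of these but shTP63 replicate 1 (up to 0.0735). LCN2 (0.38, 1.60) was lost without shControl replicate 2 or 3 or shTP63 replicate 2 or 3 (up to 0.0708). MMP7 (0.53, 1.34), a matrix metalloprotease, was lost without shControl replicate 1 or 3 or shTP63 replicate 2 or 3 (up to 0.121).

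In all, 336 genes changed the same way, 179 higher and 157 lower in both lines, where independent lists would share 76.5. Opposite calls numbered 34, where independent lists would give 77.9. Both lines share 1 variance estimate per gene, so a gene with a low estimate is called more readily in both. The 76.5 and 77.9 leave this out. Of the JHU-029 calls, 57.9% were called in FaDU in the same direction, and 233 of the 336 changed more in FaDU, with a median ratio of 1.41. Across genes, which are not independent replicates, the changes in the lines correlated at r = 0.30. The count of 336 fell to 161, 130 and 136 without JHU-029 shControl replicates 1, 2 and 3, and to 144 and 157 without JHU-029 shTP63 replicates 2 and 3. Without JHU-029 shTP63 replicate 1 it was 270, 184 of them higher in both lines. The balance of shared rises and falls was not stable. With all arrays 53.3% were higher, and 50%, 49.3% and 55% under quantile normalisation again, cyclic loess and equal medians. The share was 43.1% with each line fitted alone, and 47.8% without JHU-029 shTP63 replicate 3.

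**Figure D3:**
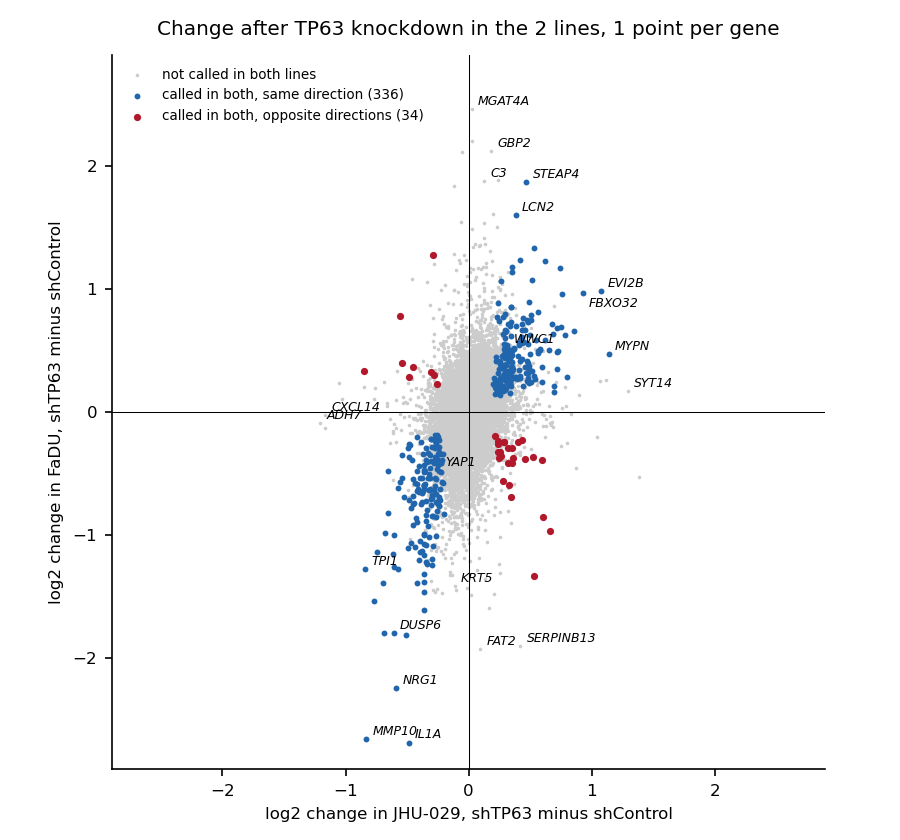
Log2 change after TP63 knockdown in JHU-029 (horizontal axis) and in FaDU (vertical axis), 1 point per gene. Genes past the threshold in both lines are blue where they changed in the same direction (336) and red where they changed in opposite directions (34); MMP10 lies at -0.83 and -2.66.

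The difference between the lines in their response was tested directly, as the FaDU change minus the JHU-029 change. The largest positive differences were those of MGAT4A (2.44, SE 0.14, adjusted p = 1.9e-06, n = 3 arrays per group), CP (2.18, SE 0.23), SLC46A3 (2.17, SE 0.12), ENPP5 (1.96, SE 0.26), GBP2 (1.94, SE 0.12), C3 (1.75, SE 0.12), SELENOP (1.65, SE 0.22), the complement factor CFB (1.61, SE 0.13), YPEL3 (1.57, SE 0.09) and the ganglioside synthase ST3GAL5 (1.54, SE 0.24). The largest negative differences were those of SERPINB13 (-2.32, SE 0.16), IL1A (-2.20, SE 0.16), FAT2 (-2.02, SE 0.16), the glutamate transporter SLC1A3 (-1.86, SE 0.11), MMP10 (-1.83, SE 0.12), VSNL1 (-1.76, SE 0.11), ADAMTS1 (-1.68, SE 0.16), NRG1 (-1.65, SE 0.18), the carbonic anhydrase CA2 (-1.63, SE 0.12) and the basal keratin KRT15 (-1.56, SE 0.15). Several of these genes were dim in JHU-029, where MGAT4A had a control mean of 4.55 and CP of 3.90 on the log2 scale, against array medians of 6.46 to 6.51. In the other direction, ADH7, whose difference was 1.12 (adjusted p = 0.00167), had a control mean of 4.89 in FaDU and 6.94 in JHU-029.

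Basal and p63-associated genes fell more in FaDU, with 23 of 37 differing downward and 0 upward (25 adjusted over the list alone, median -0.55, adjusted p = 2.69e-17), and this call held with an estimated correlation (adjusted p = 0.0405). S phase genes (12 of 38 downward, 1 upward; 20 and 1 adjusted over the list alone, median -0.20) and G2 and M phase genes (15 of 52 downward, 0 upward; 17 adjusted over the list alone, median -0.17) moved down in FaDU relative to JHU-029. Their camera adjusted p was 2.52e-06 and 4.57e-07, and adjusted p = 0.43 and adjusted p = 0.383 with an estimated correlation. Unfolded protein response genes (6 of 22 downward, 1 upward; 9 and 1 adjusted over the list alone, median -0.16, adjusted p = 0.00428, and adjusted p = 0.43 with an estimated correlation) also differed downward. Epithelial junction genes (5 of 26 downward, 2 upward; 9 and 2 adjusted over the list alone, median -0.15, adjusted p = 0.0154, and adjusted p = 0.43 with an estimated correlation) lost the call under cyclic loess (0.0705) and with genes of several lists left out (0.259). Cholesterol and fatty acid synthesis genes (3 of 27 downward, 0 upward, the same adjusted over the list alone, median -0.11, adjusted p = 0.0135, and adjusted p = 0.438 with an estimated correlation) lost it under quantile normalisation again (0.0578) and cyclic loess (0.0705), and had a median of -0.07 without JHU-029 shTP63 replicate 3.

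Interferon-stimulated genes differed upward in FaDU, with 12 of 40 (15 adjusted over the list alone), a median of 0.27 and adjusted p = 1.78e-07 (adjusted p = 0.43 with an estimated correlation). Without JHU-029 shTP63 replicate 1 the median was 0.13 (adjusted p = 5.55e-05). Simple and secretory epithelium genes (6 of 26 upward, 1 downward, the same adjusted over the list alone, median 0.17, adjusted p = 0.00428, and adjusted p = 0.231 with an estimated correlation) included MUC1 at 1.26 and MUC20 at 1.31. YAP/TAZ targets (8 of 22 upward, 3 downward; 11 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.0315, and adjusted p = 0.231 with an estimated correlation) lost the call without JHU-029 shTP63 replicate 1 (0.052) or FaDU shTP63 replicate 3 (0.0647). Hypoxia-inducible genes (7 of 24 upward, 2 downward; 11 and 3 adjusted over the list alone, median 0.22, adjusted p = 0.038, and adjusted p = 0.438 with an estimated correlation) lost it without JHU-029 shControl replicate 1 (0.0544), JHU-029 shTP63 replicate 1 (0.128), FaDU shTP63 replicate 1 (0.0883) or FaDU shTP63 replicate 2 (0.0816). Of the other 15 lists, Notch genes passed without FaDU shControl replicate 3 (0.0473). Median and mean differed in sign for the Hippo, distal 3q and mesenchymal lists. The difference passed for 2434 genes (13.2%), 915 upward and 1519 downward, and fry passed 16 of the 25 lists.

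The lines were also compared under control shRNA, which describes their starting states. In FaDU, the glutathione transferase MGST1 was 148-fold higher than in JHU-029 (log2 7.21, SE 0.06, adjusted p = 2.06e-15, n = 3 arrays per group), the kallikrein KLK6 105-fold, the protease inhibitor TFPI2 87.9-fold, SNORD61 66.1-fold, CP 55.1-fold, TMEM156 53.3-fold, the EGFR ligand EREG 50.7-fold, the serine synthesis enzyme PHGDH 45.5-fold, the simple epithelial keratin KRT19 43.9-fold and EPS8 40.4-fold. Lower in FaDU were the surface protein CD24 (182-fold; log2 -7.51, SE 0.14), the matrix protein SPARC (84.3-fold), the amino acid transporter SLC7A8 (78.8-fold), TENM2 (64.9-fold), the matrix protein TNC (58.8-fold), AMTN (57.5-fold), SMAD4, which carries TGF-beta signals (52.3-fold), the gelatinase MMP2 (50.4-fold), PTPRZ1 (46.1-fold) and the malic enzyme ME2 (45.0-fold). Many of these folds rest on low intensities in 1 of the lines, where background limits them, as for MGST1 with a mean of 3.60 in JHU-029. KRT19 (6.63) and PHGDH (6.48) lay above or near the JHU-029 array medians of 6.46 to 6.51.

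Basal and p63-associated genes were lower in FaDU controls, 27 of 37 lower and 6 higher (median -0.64, adjusted p = 1.24e-05, and adjusted p = 0.243 with an estimated correlation), and interferon-stimulated genes as well, 31 of 40 lower and 5 higher (median -0.88, adjusted p = 8.84e-05, and adjusted p = 0.633 with an estimated correlation); the counts were the same adjusted over each list alone. Mesenchymal genes were lower, 19 of 34 against 8 higher, the same adjusted over the list alone (median -0.39, adjusted p = 0.00425, and adjusted p = 0.243 with an estimated correlation). Simple and secretory epithelium genes were higher, 16 of 26 against 4 lower, the same adjusted over the list alone (median 0.33, adjusted p = 0.0209, and adjusted p = 0.26 with an estimated correlation). S phase genes (26 of 38 higher and 6 lower, 28 and 6 adjusted over the list alone, median 0.53, adjusted p = 0.000723, and adjusted p = 0.503 with an estimated correlation), G2 and M phase genes (30 of 52 higher and 13 lower, the same adjusted over the list alone, median 0.38, adjusted p = 0.0209, and adjusted p = 0.633 with an estimated correlation) and cytosolic ribosomal proteins (34 of 49 higher and 8 lower, 35 and 8 adjusted over the list alone, median 0.46, adjusted p = 0.000134, and adjusted p = 0.383 with an estimated correlation) were higher too. YAP/TAZ targets (14 of 22 lower, 7 higher, the same adjusted over the list alone, median -0.49, adjusted p = 0.0381, and adjusted p = 0.243 with an estimated correlation) and Hippo components (19 of 34 lower, 10 higher; 20 and 10 adjusted over the list alone, median -0.39, adjusted p = 0.0209, and adjusted p = 0.378 with an estimated correlation) lost their calls under quantile normalisation again (0.0683 and 0.0562) and cyclic loess (0.0886 and 0.0639) and with genes of several lists left out (0.144 and 0.0976). The lines differed in 11740 genes (63.8%), 6149 higher and 5591 lower in FaDU, a balance that turned under equal medians (46.3% higher), under cyclic loess (46.1%) and with dim probe sets left out (47.2%), and fry passed 20 of the 25 lists. Median and mean differed in sign for the keratinocyte differentiation, distal 3q, unfolded protein, heat shock, cholesterol, Notch, fibroblast and immune lists.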

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

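The counts of other splits of the arrays were planned before the data were examined, while the tests of noise, of a shared weaker response, of single arrays, of scaling, of the vector, of dim probe sets and of a few members were chosen only after the results were seen. Groups of 3 arrays were not tested for outlying samples. Array weights ran from 0.548 (FaDU shControl replicate 2) to 2.10, and JHU-029 shTP63 replicate 1 had 0.596 where the others of its group had 2.10 and 1.30. The results given here differ between the cell lines under the same contrast or lie in probe sets outside the gene tests.

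The knockdown effect differed between the lines for 2434 genes. Of 100 splits within both lines (of 200 possible), 3 gave as many, the real one included, and the highest other count was 2541. The 9 draws that kept the FaDU groups and mixed the JHU-029 arrays gave 1853 to 2541, while 11 draws that kept the JHU-029 groups gave at most 12 and 79 that mixed both gave at most 0. Of those 9 draws, 2 reached the real count, while the 11 and 79 further draws broke the FaDU groups. The count therefore follows the FaDU groups, and these splits decide nothing about chance or about a JHU-029 response. For the 336 genes changed the same way in both lines, 1 of 100 splits gave as many, the real one, with 0 as the highest other count. In each other split at least 1 of the lines had 0 calls by limma, so nothing could be shared, and these splits do not test sharing. For 580 genes in JHU-029, 4901 in FaDU and 11740 between the controls, the 10 splits of 6 arrays are too few for a share under 0.05; the real split alone reached the count (1 of 10 each) and the highest other count was 0.

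Far fewer genes passed in JHU-029 (580) than in FaDU (4901). Noisier JHU-029 arrays in general are argued against, since the median SD within its groups was 0.757 of that in FaDU. Fitting each line alone, with its own spread, still gave 819 against 3557 genes. Single deviating arrays are not covered by these values. Array weights were 0.596 for JHU-029 shTP63 replicate 1, 1.13 to 2.10 for the other JHU-029 arrays and 0.548 to 0.958 for FaDU. They gave 2017 against 4233 genes. Since they also weigh the 2 lines unequally, the 2017 cannot be laid to that array alone. Leaving out JHU-029 shTP63 replicate 1 gave 485 against 4926. How much single arrays add to the gap thus stays open. For a single response, merely weaker in JHU-029 through weaker depletion of TP63, opposite calls should not exceed false calls. Here 34 genes passed in both lines in opposite directions, where independent false calls would give 7.72 (upper limit 14). Both lines share 1 variance estimate per gene and genes are not independent, so false calls may cluster and this limit may be too low. The limit alone therefore does not decide. All 34 also passed the test of the difference between the lines. Among JHU-029 calls with a called difference, 135 changed more in JHU-029, 22 of them called in FaDU too. False calls aside, a response merely weaker in JHU-029 gives neither, so these values argue against it for these genes. Some, such as ADH7 (4.89 in FaDU controls), were dim in FaDU, where a change may be hidden. For the other genes a shared, weaker response stays open. How far p63 itself fell in each line stays open, as does a biological difference between the lines, which was not tested apart from it, so part of the gap may come from either.

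Interferon-stimulated genes rose in FaDU (median 0.35; adjusted p = 0.365 with an estimated correlation) and differed between the lines (0.27, or 0.13 without JHU-029 shTP63 replicate 1; adjusted p = 0.43 with an estimated correlation). A single FaDU array is argued against, since leaving out any 1 of the 6 FaDU arrays gave medians of 0.30 to 0.36, and so is scaling, since cyclic loess gave 0.37. FaDU knockdown arrays had list means of 0.36 or more and control arrays of 0.0231 or less. The controls carried a control vector, so a response common to both vectors would largely cancel. An effect of the shRNA against TP63 other than loss of p63 cannot be told apart from a p63 effect, since JHU-029 received an shRNA against TP63 too. A rise there would follow from either, and the JHU-029 median was 0.064, with the list not passing. In JHU-029 the list passed by camera with the preset correlation once shTP63 replicate 1 (median 0.12) or shControl replicate 1 (median 0.10) was left out. A smaller response there may thus be hidden by single arrays, and a biological difference between the lines stays open as untested.

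YAP/TAZ target genes were higher in FaDU as a list (median 0.24; adjusted p = 0.122 with an estimated correlation, which loses the call), with 13 of 22 rising and 2, FJX1 and GADD45A, falling, while YAP1 itself fell. A few members as the cause are argued against by those 13, and so are dim probe sets, since 12 of those 13 lay above the array medians in all FaDU arrays. Scaling is argued against by a median of 0.27 under cyclic loess, and leaving out any 1 FaDU array gave 0.22 to 0.28. Activity of YAP1 or TAZ protein was not measured here, so whether the rise reflects their activity or another regulator of these genes may not be read from these arrays and stays open, as does the effect of the line.

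Single genes differed between the lines as follows, in FaDU minus JHU-029 log2 change. MGAT4A differed by 2.44, CP by 2.18, SLC46A3 by 2.17, ENPP5 by 1.96 and GBP2 by 1.94. C3 differed by 1.75, SELENOP by 1.65, CFB by 1.61, YPEL3 by 1.57 and ST3GAL5 by 1.54. All of these but YPEL3 and ST3GAL5 had both JHU-029 group means below the JHU-029 array medians, where a change may be hidden. On the negative side stood SERPINB13 at -2.32, IL1A at -2.20, FAT2 at -2.02, SLC1A3 at -1.86 and MMP10 at -1.83. VSNL1 stood at -1.76, ADAMTS1 at -1.68, NRG1 at -1.65, CA2 at -1.63 and KRT15 at -1.56. KRT5 differed by -1.30, KRT14 by -0.38 and YAP1 by -0.24, and the last 2 lost the call in 7 and 9 of the 12 fits without 1 array (adjusted p of up to 0.08 and 0.0978). Of 155 genes named for the line comparisons, 114 had a called difference.

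Among the gene lists, the median difference was -0.55 for basal and p63-associated genes, -0.20 for S phase genes, -0.17 for G2 and M phase genes, -0.16 for unfolded protein response genes, -0.15 for epithelial junction genes and -0.11 for cholesterol and fatty acid synthesis genes. It was 0.27 for interferon-stimulated genes, 0.24 for YAP/TAZ targets, 0.22 for hypoxia-inducible genes and 0.17 for simple and secretory epithelium genes. Of these 10 lists, 1 kept its call with an estimated correlation, that of the basal and p63-associated genes (adjusted p = 0.0405). The YAP/TAZ and hypoxia lists also lost the call without certain single arrays (adjusted p of up to 0.0647 and 0.128), and the epithelial junction and cholesterol lists under cyclic loess (adjusted p = 0.0705 for both). Among the 13162 probe sets without a single gene symbol, 64 changed in JHU-029 and 1033 in FaDU, 35 of them in both lines in the same direction.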

How the results depend on the processing

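Leaving out the 2 FaDU controls with an extra title word, and the scalings and single arrays for the lists, were tests chosen only after the results were seen. The main counts were 580 genes in JHU-029, 4901 in FaDU, 336 changed the same way, 2434 differing between the lines and 11740 between the controls. Under a robust prior, the mean of probe sets, a random replicate block and 3 other scalings, all 5 counts stayed within 1.5 times of these. With the replicate number as a fixed block, which takes up degrees of freedom, the counts were 172, 4076, 95, 1396 and 11249. Adjusted p in JHU-029 was then 0.0945 for WWC1 and 0.125 for YAP1. Whether the numbers pair the arrays is not given in the labels. The random block had a consensus correlation of -0.13, and with a negative value blocking widens the error of a knockdown effect. A trend in the prior gave 1015 genes in JHU-029 and 579 shared, and array weights 2017 and 835; the cause was not tested. Leaving out dim probe sets, with 12150 genes tested, gave 880 and 524. Every probe set tested as its own item gave 17975 between the controls, from 32321 tested. The stricter adjusted p under 0.01 gave 195, 106 shared and 1183 differing, and a 2-fold minimum 11, 156, 0, 124 and 2833, since they ask for more; limma without that minimum called 336 shared genes. Leaving out 1 array gave 229 to 626 in JHU-029, 4322 to 4926 in FaDU, 130 to 354 shared, 1704 to 2510 differing and 10726 to 11870 between controls, the lowest JHU-029 and shared counts coming from the fits without JHU-029 shControl replicates 3 and 2, with 2 arrays left in that group. Without the 2 FaDU controls, where the lone control is assumed to vary like the other groups, the counts were 646, 3569, 305, 1928 and 9965. Of 225 named changes past the threshold, 44 lost the call in at least 1 fit without 1 array. Changes of 3 uncalled genes in JHU-029 turned sign: ACTL6A was at -0.0010 with array weights, -0.0073 after quantile normalisation again and -0.0093 with cyclic loess, and without 1 array ACTL6A ran from -0.0285 to 0.0254, CCN2 from -0.0075 to 0.0859 and KRT14 from -0.102 to 0.0073; the cause was not tested. For the lists, fry gave the other direction than camera between the controls for keratinocyte differentiation (median 0.0519), epithelial junction (-0.23) and fibroblast markers (0.0679); it compares no other genes. The other scalings moved the median of all genes by at most 0.07. An alternative without probe sets ending in _x_at was not run, since 0 carry that ending, and those for the level of TP63 give no value. Dim genes, near the background of an array, limit the folds between lines.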

Other observations

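The tests of gene families and of neighbouring genes were all chosen only after the results were seen, and the genes named here were chosen after their values were seen. Families were formed from shared symbol stems, and 329 with at least 8 measured members were tested with camera. In FaDU, 14 families passed after TP63 knockdown, all with a median below 0 on the deposited scale and under each of the 3 other scalings, 12 of them past the threshold under each scaling (highest adjusted p 0.0601). Of 15 genes with the metallothionein stem MT, 12 fell, MT1F at -0.66 (SE 0.09) and MT1X at -0.53 (SE 0.08) among them. Metallothioneins bind zinc and copper, but the stem also takes in the pseudogenes MT1DP, MT1IP, MT1JP and MT1P3. The median was -0.32, with a camera adjusted p = 5.37e-05, but adjusted p = 0.978 with an estimated correlation. No list of ribosome synthesis genes was tested. By symbol stem, single genes past the threshold were 9 of 10 UTP genes (UTP20 at -0.54, SE 0.07), 7 of 9 RRP genes (RRP12 at -0.69, SE 0.08), 7 of 11 NOL genes (NOL6 at -0.67, SE 0.07) and 7 of 10 EXOSC genes (EXOSC2 at -0.49, SE 0.05), all lower, and the NOL stem also takes in NOL3, NOL4 and NOL4L. As families these calls were lost, with adjusted p = 0.578 with an estimated correlation for RRP and adjusted p = 0.978 with an estimated correlation for the other 3. RNA polymerase genes fell in 14 of 31 members, POLR1H at -0.89 (SE 0.09) and POLR1G at -0.69 (SE 0.05), both subunits of the polymerase that transcribes ribosomal RNA. Mitochondrial ribosomal proteins fell in 18 of 48 MRPL and 11 of 26 MRPS members, MRPS14 at -0.83 (SE 0.12), and 10 of 14 TIMM genes of mitochondrial protein import fell and 1 rose. The other 5 families, with stems MCM, EIF, DDX, NUP and TRMT, had adjusted p between 0.00478 and 0.0218. With an estimated correlation adjusted p was 0.578 for RRP and 0.978 for the other 13, so these calls were lost. In JHU-029, small nucleolar RNAs moved down, 3 of 115 SNORD genes (median -0.06, adjusted p = 0.0381) and 2 of 61 SNORA genes (median -0.09, adjusted p = 0.0439), lost with an estimated correlation (adjusted p = 0.988 for both).

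Between the control arrays, genes that differed strongly lay side by side on chromosomes. Among 16241 protein-coding autosomal genes in reference order, 5 runs of at least 4 neighbours differed in the same direction by at least 1.5 on the log2 scale. Lower in FaDU were AKR1E2, AKR1C1, AKR1C2 (-4.52, SE 0.16) and AKR1C3 on chromosome 10, steroid- and carbonyl-reducing enzymes. COMMD9, PRR5L (-3.21, SE 0.15), TRAF6 and RAG1 on chromosome 11, and C12orf75, NUAK1 (-3.75, SE 0.14), CKAP4 and TCP11L2 on chromosome 12, were lower as well. On chromosome 18, ME2 (-5.49, SE 0.09), ELAC1, SMAD4 (-5.71, SE 0.13) and MEX3C (-4.05, SE 0.19) were lower. Higher in FaDU were FADD, PPFIA1 (2.52, SE 0.06), CTTN (2.89, SE 0.06) and SHANK2 on chromosome 11. A chance order of single-gene differences is argued against, since 0 of 1000 shuffled orders gave as many runs (at most 2, mean 0.114). A loss of the region around SMAD4 in FaDU may account for the run on chromosome 18, but DNA was not measured here: the highest mean among its members in FaDU controls was 5.97, below the lowest array median of 6.52, which a silenced region would show too, so the explanations cannot be told apart.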
